A study of Mus musculus with 3 samples.

How the data were processed

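Small RNAs were profiled in mouse oocytes, spermatozoa and zygotes, with 1 library per group. Per the labels' protocols, total RNA was isolated with TRIzol, libraries were made with Illumina protocols and sequences of 18 to 32 nt were reported. Oocytes and zygotes came from the oviducts of superovulated females and were freed of cumulus cells and of the zona pellucida. The labels describe the oocytes both as fully grown and as at metaphase II, and they give the sire strain of the zygotes as DBA/6J.

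The 6 expression profiles, 3 of piRNAs and 3 of endo-siRNAs, list identifiers with a signal, not counts. This signal was made by the authors with a trimmed mean of M values (TMM), per the file headers. The submitters' processing notes name Bowtie 0.12.9, DESeq with no version and the genome build mm9, with no role given for each. The trimming method of the headers and the DESeq of the notes are different scaling methods, and which was applied is not given in the sources used here. The low values fell on steps of 1 read divided by whole numbers. The signal worth 1 read was 0.813 in the oocyte, 1.14 in the spermatozoal and 1.12 in the zygote library, the same for both classes. Divided by this step, the class totals came out within 0.0577 of a whole number. Of the single values, 18.7% to 30.4% were whole in the piRNA profiles and 8.62% to 9.00% in the endo-siRNA profiles, at a tolerance of 0.01. Reads that match several identifiers were thus split between them, and neighbouring identifiers can hold shares of the same reads. Levels below are read equivalents per 1000000 of the class in a library (RPM), which do not depend on the step. The lists hold only identifiers with a value above 0, so an identifier that is missing is called not listed.

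The 5 lists of ping-pong pairs give read counts per distinct sequence, per the file headers, from 2 counts up and not normalized. Ping-pong pairs are piRNAs of opposite strands whose 5′ ends overlap by 10 bases. In the 10A lists, made for all 3 libraries, first members had A at position 10 and a first base other than U, and second members began with U. In the 5U10A lists, used here for spermatozoa alone, members had both U at position 1 and A at position 10. In all lists, 100% of the pairs were complementary over the 10 bases. The names come from the RNAdb set (PIR numbers) or the deepBase set (mmur numbers) of piRNAs. Items are called piRNAs below by these names alone, and whether their reads are piRNAs was not tested.

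The design had assumed counts in the profiles; since they hold a scaled signal, a minimum of 100 RPM in the higher library replaced the minimum of 100 counts, as the design allowed. With 1 library per group there was no replicate check, and no p-value or SD was computed. Read totals carry exact Poisson intervals, ratios of totals their exact conditional intervals and shares Clopper-Pearson intervals, all at 95%. The intervals treat each read, or each item or distinct sequence in a share of those, as an independent draw. They leave out differences between libraries, reads split between identifiers, and repeated copies of a molecule, since the reads carried no molecular identifiers. A ratio against an identifier that is not listed is not given.

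Detection, the gamete lists that hold each zygote item, Pearson and Spearman correlations across items of log2(RPM + 1), and changes of at least 4-fold were computed for each class. The totals were 24756486, 18728064 and 22075046 read equivalents of piRNAs in oocyte, spermatozoa and zygote, and 16074372, 1555582 and 18753351 of endo-siRNAs. A level of 100 RPM thus rests on 1873 to 2476 read equivalents of piRNAs, and on 1607, 156 and 1875 of endo-siRNAs. The sum of 3 reads, used as the floor, corresponds to 0.121, 0.16 and 0.136 RPM of piRNAs and to 0.187, 1.93 and 0.16 RPM of endo-siRNAs.

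Distinct sequences of the pairs lists, 61356 in all, were matched without mismatch to both strands of the GENCODE M21 transcripts of GRCm38, and 34.4% matched. These matches give the gene names and coordinates below; the mm9 coordinates of the identifiers were not used here. The transcripts used hold no nuclear tRNAs, so a sequence that matched no transcript is not without an origin. Partners at other overlaps were counted on an 8-base window inside the overlap.

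Items were named by a rule set before the data were examined: the 10 highest of each class in each library, up to 5 with the largest ratio each way for each pair of libraries at 100 RPM or more, and the 5 pairs and 5 members with the most reads or pairs. The lists fixed at the same time were matched to sequences that match a single gene. Of 15 source genes of endo-siRNAs, Mad2l1 alone matched, with 5 reads in the oocyte and 3 in the zygote 10A list. Of 11 genes of the piRNA and RNA interference pathways, Dicer1 matched 2 reads in the oocyte 10A list, Dicer1 and Ago2 together 11 in the zygote 10A list, Ago2 alone 16 in the spermatozoal 10A list and 27 in the spermatozoal 5U10A RNAdb list, and Piwil2 2 reads in the 5U10A deepBase list. The markers of cumulus and granulosa cells (15 genes), oocytes (5), spermatogenic cells (2), epididymis (1), and epithelium and blood (3) matched 0 reads in the 5 lists. These lists hold only piRNA-named reads, so they are no measure of contamination or of endo-siRNAs from the source genes. Reads that match more than 1 gene, such as a gene and its pseudogene, were left out of these counts. Repeat families are not named in the profiles, so their list gave no value. The fixed lists also named Fbxw, Defb and the pachytene piRNA clusters, which were not matched, so the 0 reads do not cover them.

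The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and TMM factors for an alternative came from edgeR 4.0.16 in R 4.3.3. The rule for changed items was tested on simulated data for zygote against oocyte, with 200 items changed in each class. At 8-fold it recovered 100% of them. At 4-fold, which lies on the threshold, it recovered 49.0% of the piRNAs and 50.0% of the endo-siRNAs, with 0 other calls. The simulated counts held counting error only, so these shares do not cover other differences between libraries or reads split between identifiers. Transcript matching recovered 100% of 400 simulated matches. Partners at an overlap of 10 bases were found for 100% of 400 simulated sequences, which the planting of these pairs ensured. At another overlap at most 29 of 1200 sequences had a partner by chance. The alternatives were other count minimums, pseudocounts, scalings, fold and level thresholds, equal depth, weighting by items or reads, and other definitions of pairs. The length and first base of endo-siRNAs were not analysed here, since the profiles pair no sequences with the identifiers.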

Results

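The data set profiled 2 classes of small RNA in mouse germ cells and in the embryo they form. piRNAs are small RNAs bound by PIWI proteins that silence transposons in the germ line, and endo-siRNAs are small RNAs cut by Dicer from endogenous double-stranded RNA. The groups were metaphase II oocytes of C57BL/6 mice (15210 cells), spermatozoa from the cauda epididymis of CD-1 mice, and zygotes collected 15 to 18 hours after fertilization from C57BL/6 females mated with males of another strain (15416 cells). Each group had 1 library, so the differences below are between libraries and have no replicate check; strain and number of cells differ with the group. The question was what each gamete contributes to the piRNAs and endo-siRNAs of the zygote.

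The oocyte and zygote libraries held both classes in similar amounts, and the spermatozoal library held mostly reads listed under piRNA names. Endo-siRNAs made up 39.4% of the read equivalents of both classes in the oocyte, 45.9% in the zygote and 7.67% (95% interval 7.66% to 7.68%) in spermatozoa. Against deepBase piRNAs alone, without the RNAdb set, the gap was smaller. There were then 1.22 endo-siRNA reads per piRNA read in the oocyte, 1.34 in the zygote and 0.710 in spermatozoa. There were 90375 piRNAs listed in the oocyte, 83167 in spermatozoa and 92048 in the zygote. For endo-siRNAs the numbers were 196120, 102208 and 203288. At equal depth, drawn as whole reads, the endo-siRNA numbers were 83791, 64309 and 83186. The spermatozoal number falls too, since identifiers with a fraction of a read drop out.

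The named sets of piRNAs differed more between gametes than the totals did. RNAdb piRNAs numbered 46486 in spermatozoa, against 4027 in the oocyte and 4318 in the zygote, and took 88.3% of the spermatozoal piRNA reads, against 46.7% in the oocyte and 36.6% in the zygote. The others were deepBase piRNAs. In spermatozoa a few names held most of the signal: PIR64428 took 37.9% of it, PIR64875 6.90% and PIR64874 6.84%, and these 3 names reached 50%. In the oocyte the leading name was PIR65416 with 7.32%, and 61 piRNAs took 50%. In the zygote the leading name was PIR32924 with 5.27%, and 159 piRNAs took 50%. The 10A list of spermatozoa covers 2.75% of the reads of PIR64428, led by ACGACTCTTAGCGGTGGATCACTC with 110641 counts, which matched no transcript. For PIR65416 in the oocyte the list covers 0.0413% of the reads, so its main sequence is not known here. PIR64874 and PIR64875 had the same leading sequence in the spermatozoal 10A list, with 2818 counts, so these names share reads. That sequence begins with the bases that end the leading sequence of PIR64428. The 3 leading names of spermatozoa thus need not be separate RNAs. The list covers only 0.0936% of the reads of PIR64874 and 0.117% of PIR64875. A name in these sets does not by itself show that the reads are piRNAs, and whether they are fragments of rRNA or tRNA was not tested.

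Among endo-siRNAs, endo_mmur001272954 led in both the oocyte and the zygote, with 25.2% and 28.0% of the class, and had 367 RPM in spermatozoa. The identifiers endo_mmur001273848 to endo_mmur001273859, 12 neighbours by number, added 16.3% in the oocyte and 13.99% in the zygote but 0.0194% in spermatozoa. In spermatozoa no identifier reached such a share, and endo_mmur000483664 led with 1.16%. It had 9 read equivalents in the oocyte and was not listed in the zygote.

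Most zygote small RNAs were also listed in the oocyte. Of the 92048 zygote piRNAs, 52.8% (52.5% to 53.1%) were listed in the oocyte and not in spermatozoa, and 30.5% (30.2% to 30.8%) in both gametes. Spermatozoa alone listed 3.06% (2.95% to 3.18%), which were 2819 piRNAs, and neither gamete listed 13.6% (13.4% to 13.8%). By zygote signal the shares were 18.0% for oocyte alone, 81.9% for both gametes, 0.0226% for spermatozoa alone and 0.106% for neither. An item counts as listed at any value above 0, so the share of both gametes includes items almost absent from spermatozoa. The 14 neighbours mmur000220580 to mmur000220593, for example, were listed in both gametes, with 9425 RPM in the zygote and 0.833 in spermatozoa. With at least 10 read equivalents required in each library, both gametes listed 11.2% of the zygote piRNAs. The median level of the piRNAs shared with spermatozoa alone was 1 read equivalent in the zygote, against 8.82 for those shared with the oocyte alone. Among the 4318 zygote piRNAs of the RNAdb set, spermatozoa alone listed 16.9% (15.8% to 18.0%), the oocyte alone 16.7% (15.6% to 17.8%), both gametes 51.6% (50.1% to 53.1%) and neither 14.8% (13.8% to 15.9%). By signal these were 0.0199%, 1.43%, 98.5% and 0.0224% of the set.

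Zygote endo-siRNAs divided in a similar way. Of the 203288 listed, 48.8% (48.5% to 49.0%) were listed in the oocyte alone, 38.8% (38.5% to 39.0%) in both gametes, 2.79% (2.72% to 2.86%) in spermatozoa alone and 9.69% (9.56% to 9.82%) in neither. Their shares of the zygote signal were 24.9%, 74.9%, 0.0285% and 0.156%. The 12 neighbours endo_mmur001273848 to endo_mmur001273859 were listed in both gametes and so count toward the 74.9%. They held 13.99% of the class in the zygote but 0.0194% in spermatozoa. At equal depth the endo-siRNAs of both gametes were 19.8% of the zygote list, and with at least 10 read equivalents required they were 5.21%. At equal depth the endo-siRNAs listed with spermatozoa alone were 6.43% of the zygote list. With at least 10 read equivalents required, they were 0.478%, and the piRNAs listed with spermatozoa alone were 0.687%.

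**Figure D1:**
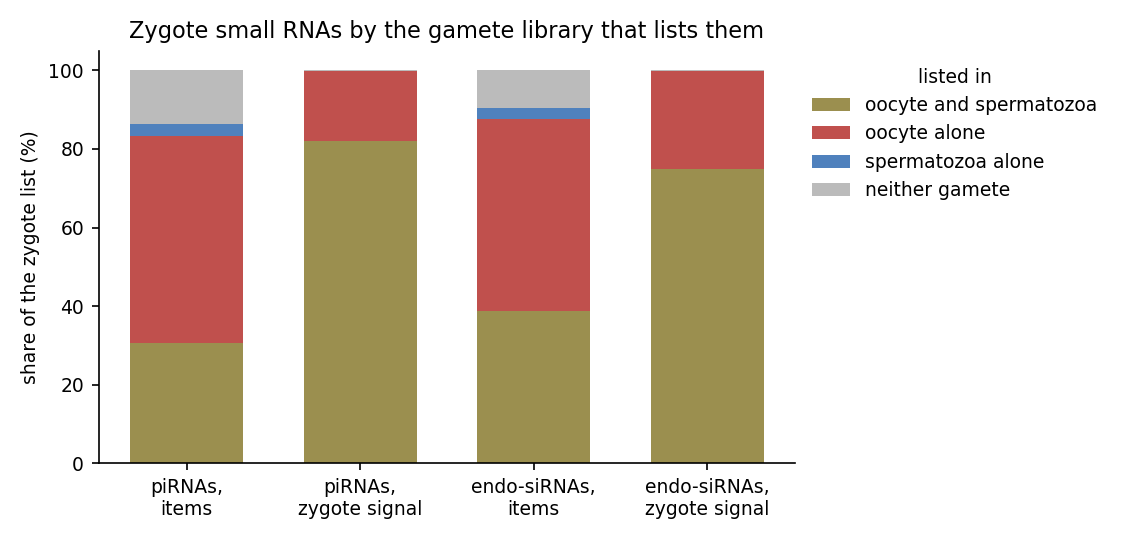
Share of the zygote list, in percent, by the gamete library that also lists each small RNA, for piRNAs and endo-siRNAs, with each item counted once or weighted by zygote signal. Spermatozoa alone account for 3.06% of zygote piRNAs and 2.79% of zygote endo-siRNAs by number, and for 0.0226% and 0.0285% of the signal.

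Seen from the gametes, 84.9% (84.6% to 85.1%) of oocyte piRNAs were listed again in the zygote and 37.1% (36.8% to 37.5%) of spermatozoal piRNAs. The same spermatozoal piRNAs were listed in the unfertilized oocyte at 37.7% (37.4% to 38.05%). Of the spermatozoal RNAdb piRNAs, 6.36% (6.14% to 6.58%) were listed in the zygote and 6.21% (6.00% to 6.44%) in the oocyte. Spermatozoal endo-siRNAs were listed in the zygote at 82.6% (82.4% to 82.9%) and in the oocyte at 82.3% (82.0% to 82.5%). These shares include fractions of reads and were not computed at equal depth. At equal depth, endo-siRNAs of both gametes fell from 38.8% to 19.8% of the zygote list, and piRNAs from 30.5% to 24.8%. The shares of the classes are thus not compared here on equal terms.

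The zygote profile lay close to that of the oocyte and far from that of spermatozoa. Across 154715 piRNAs, Pearson's r of the log2 levels was 0.977 between zygote and oocyte, 0.101 between zygote and spermatozoa and 0.147 between oocyte and spermatozoa; Spearman's rho was 0.833, -0.38 and -0.34. Across 233930 endo-siRNAs, r was 0.961, 0.0609 and 0.0998, and rho was 0.848, -0.0814 and -0.00303. Of the piRNAs listed in both libraries compared and with at least 100 RPM in any of the 3, 80.1% lay within 2-fold between zygote and oocyte and 4.20% between zygote and spermatozoa; for endo-siRNAs the shares were 80.3% and 0.226%. These correlations are across items, which share reads and are not independent replicates. Among items with at least 10 read equivalents in a library, the r between zygote and spermatozoa turned negative, at -0.109 for piRNAs and -0.13 for endo-siRNAs. An item missing from a list counts as 0 in these correlations. Across items listed in both zygote and spermatozoa, r was 0.240 for piRNAs and 0.110 for endo-siRNAs, and rho was 0.280 and 0.204. For oocyte and spermatozoa, r was then 0.300 and 0.155, and rho 0.316 and 0.241. The sign thus depends on which items are kept.

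**Figure D2:**
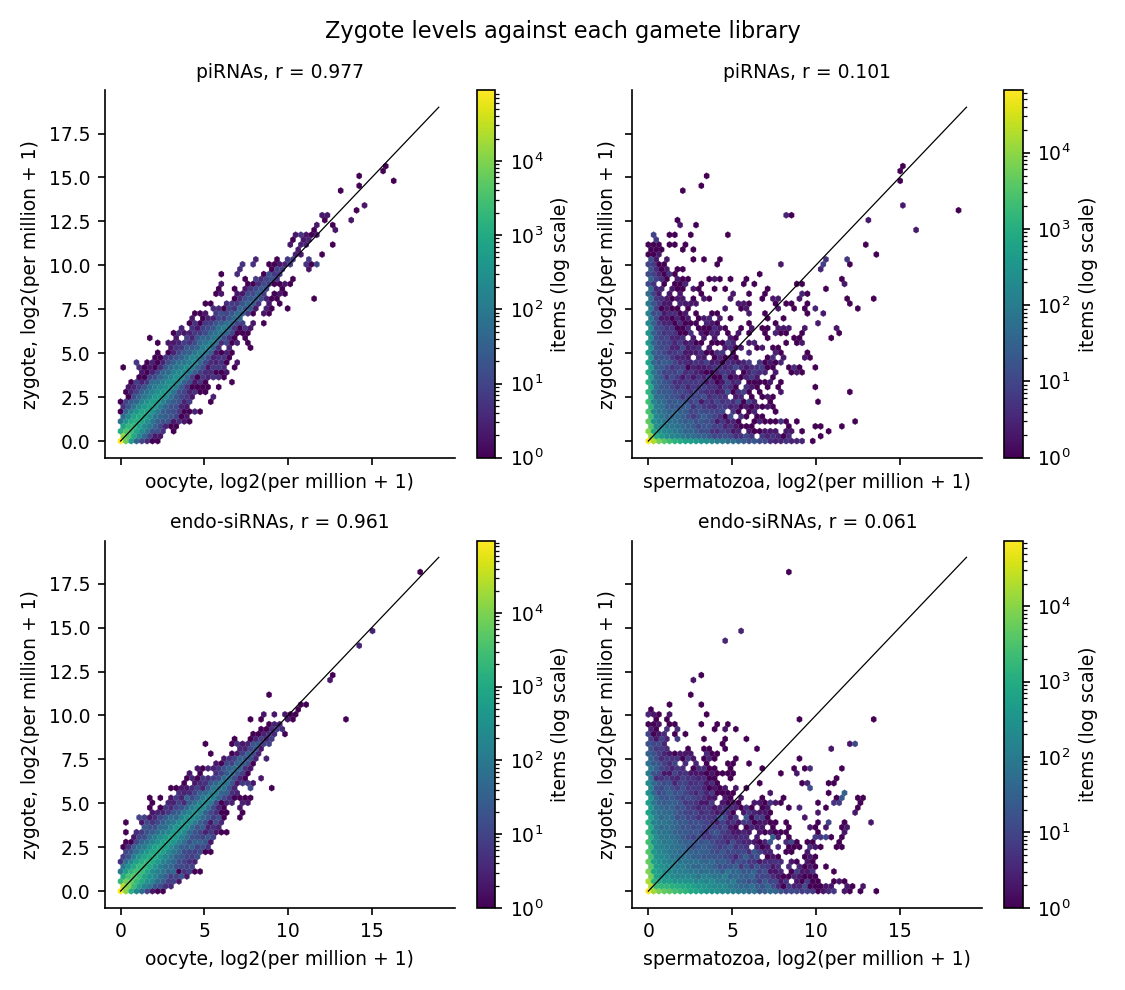
Level of each small RNA in the zygote against the oocyte and against spermatozoa, as log2(RPM + 1), with hexagons coloured by the number of items on a log scale and a line at equal levels. Zygote and oocyte levels lie along the line, with r = 0.977 for piRNAs and 0.961 for endo-siRNAs, and zygote and spermatozoal levels do not, with r = 0.101 and 0.0609.

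Few abundant piRNAs differed between zygote and oocyte by 4-fold or more: of 1185 with at least 100 RPM, 41 were higher in the zygote, 8 were lower and 1136 differed by less. The largest rise among these was of mmur000080602, from 66.3 to 738 RPM, 11.1-fold (10.6 to 11.7), with 90.8 in spermatozoa. PIR58507 and PIR58508 went from 66.2 and 66.3 to 507 and 508 RPM, 7.67-fold (7.28 to 8.08) and 7.65-fold (7.26 to 8.06). mmur001227778, at 60.6 against 422 RPM, and mmur001227777, at 34.5 against 239, were next, and neither was listed in spermatozoa. The 14 listed neighbours mmur000220580 to mmur000220593 rose from a sum of 1478 to 9425 RPM, and had 0.833 RPM in spermatozoa. Neighbours can hold shares of the same reads, so neither these 14 nor the 41 higher piRNAs need be separate rises.

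Among piRNAs with at least 100 RPM in either library, the largest fall was of PIR58266, from 3330 to 262 RPM, 12.7-fold (12.4 to 13.1). PIR65949 fell from 107 to 9.26 RPM, and PIR65950 and PIR65951 each from 135 to 20.5. mmur000400087 fell from 121 to 16.8 RPM. The leading sequence of PIR65949, PIR65950 and PIR65951 in the oocyte was the same, CTCGGTAGTATAGTGGTCAGTATCCC with 5307 counts, so these 3 names share reads. On the deposited scale the zygote values stood 0.29 higher on the log2 scale relative to the oocyte, and 50 piRNAs were higher and 7 lower. With TMM factors, 27 were higher and 9 lower.

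For endo-siRNAs the split between higher and lower depended on the scaling. Relative to the class total, 8 of 854 endo-siRNAs were higher in the zygote than in the oocyte and 26 lower, so that 23.5% of the changed items were higher. On the deposited scale, which stood 0.68 higher on the log2 scale, 23 were higher and 3 lower (88.5%), and with median-of-ratios factors 21 and 5 (80.8%). With TMM factors computed here, 8 were higher and 26 lower, as relative to the class total. The named items kept their direction under these scalings. Among the 854, the largest rise was of endo_mmur001325976, from 31.9 to 367 RPM, 11.5-fold (10.5 to 12.6), followed by endo_mmur001197795, from 14.7 to 105, and endo_mmur001197800, from 16.3 to 104. The largest fall was of endo_mmur001132931, from 11234 to 798 RPM, 14.1-fold (13.8 to 14.3), with 10909 RPM in spermatozoa. endo_mmur000495088 fell from 560.5 to 58.0 RPM and endo_mmur001428758 from 139 to 19.7.

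Zygote and spermatozoa differed in nearly all abundant small RNAs. Of 1348 piRNAs, 1066 were higher in the zygote and 206 in spermatozoa by 4-fold or more, and 76 differed by less. Higher in the zygote were mmur000190620, at 3289 against 0.215 RPM, and mmur000681039 and mmur000681041, at 3160 and 3396 against 0.215 and 0.25 RPM. These were also high in the oocyte, at 1871, 1840 and 1979 RPM. Higher in spermatozoa were PIR224172, at 3233 against 0.664 RPM in the zygote, 4866-fold (2884 to 8501), and mmur000776932, at 1387 against 0.272, 5105-fold (2345 to 13912). Spermatozoa had 5716 RPM of mmur000042018, against 1.25 in the zygote and 17.6 in the oocyte. mmur000001579, at 816 RPM in spermatozoa, was not listed in either the oocyte or the zygote.

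Of 1599 endo-siRNAs, 719 were higher in the zygote and 867 in spermatozoa; on the deposited scale, whose zygote total stood 3.56 higher on the log2 scale, the numbers were 728 and 701. Higher in the zygote was endo_mmur001273848, at 4499 against 5.79 RPM, 778-fold (409.6 to 1701). Higher in spermatozoa were endo_mmur000044222, at 6682 against 0.24 RPM, and endo_mmur001237608, at 6874 RPM and not listed in the zygote or the oocyte. The direction of these 3 did not change on the deposited scale. A spermatozoal level of 100 RPM rests on 156 read equivalents of this class, so the lower end of that profile is less precise.

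Oocyte and spermatozoa differed in the same manner. Of 1138 piRNAs, 854 were higher in the oocyte and 170 in spermatozoa. mmur000161786 had 1978 RPM in the oocyte and 2 read equivalents in spermatozoa. PIR219263 had 1397 RPM in spermatozoa and 0.283 in the oocyte, 4941-fold (2398 to 12290). Of 1558 endo-siRNAs, 677 were higher in the oocyte and 850 in spermatozoa. endo_mmur001273856 had 7076 RPM in the oocyte and 7.07 in spermatozoa.

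The lengths of 10A piRNA reads differed between the oocyte and spermatozoa, and the zygote resembled the oocyte. With each distinct sequence counted once, the commonest length was 21 nt in the oocyte (18.3%) and the zygote (18.3%) and 28 nt in spermatozoa (9.71%). Reads of 25 to 32 nt, the size of piRNAs, were 35.4% (34.4% to 36.4%) of the distinct sequences in the oocyte, 33.1% (32.2% to 34.0%) in the zygote and 55.1% (54.1% to 56.1%) in spermatozoa. Weighted by counts, they were 22.2% (22.1% to 22.3%), 22.3% (22.2% to 22.4%) and 42.5% (42.4% to 42.7%). The sequence CGCGACCTCAGATCAGAC of 18 nt, listed for PIR7717, alone had 303490 counts in the oocyte and 532750 in the zygote, against 13177 in spermatozoa. In these lists A was the first base of 28.1% of the reads in the oocyte, 28.7% in the zygote and 62.2% in spermatozoa, but of 47.3%, 49.1% and 31.7% of the distinct sequences. So the order of the libraries in this share turned with the weighting, and first bases of U are left out of the 10A first members by construction.

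**Figure D3:**
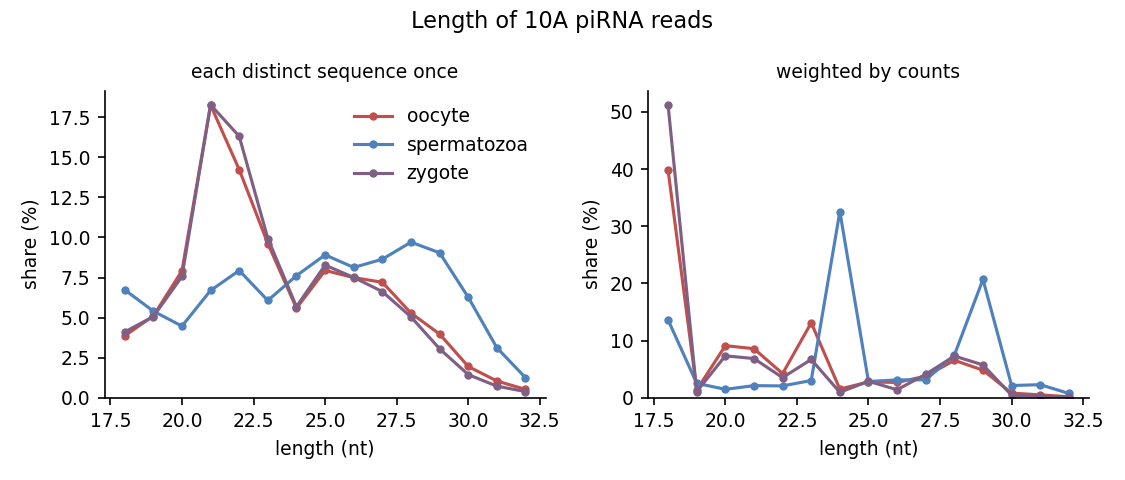
Length in nt of the first members of the 10A lists, as percent of distinct sequences and as percent of counts, for the 3 libraries. Distinct sequences peak at 21 nt in oocyte and zygote and at 28 nt in spermatozoa, and 18-nt reads take 39.8% of the oocyte and 51.2% of the zygote counts.

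Pairs of the ping-pong form were listed in all 3 libraries. Partners at other overlaps were not counted for the 10A lists, so an excess at 10 bases was not tested in them. The 10A lists held 30478 pairs in the oocyte, 23775 in spermatozoa and 42130 in the zygote. A partner was listed for 26% (25.1% to 26.9%) of the distinct first members in the oocyte, 29.3% (28.4% to 30.2%) in spermatozoa and 31.7% (30.8% to 32.6%) in the zygote. Weighted by reads, the shares were 13.0%, 14.8% and 23.1%. Many pairs were length and sequence variants of the same 5′ ends: the distinct pairing 5′ ends, taken as the first 10 bases, numbered 386, 861 and 486, so the order of the libraries changed. In spermatozoa the repeat CACACACACA gave 9936 pairs, 41.8% of the list, and 13839 remained without it. In the oocyte GTGAGTTCCA gave 4686 pairs and CATCACCAAA 4615, and in the zygote GTGAGTTCCA gave 5580 and GTGATGAACA 4743.

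The best supported pair of the oocyte joined ATAATAGCCAGAAGATGGAAAGAACCTA of PIR198770, with 486 counts, to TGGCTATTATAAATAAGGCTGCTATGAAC of PIR15329, with 539 counts. The same pair led in the zygote, with 492 and 819 counts. In spermatozoa the best supported pair joined ATCTGTGAAATGAGGGAGTTGGACTAGA, with 159 counts, to TTTCACAGATGAGGAAACTGAAGCTTAG, with 224 counts. Of the pairs whose members both matched transcripts, 45.3% (44.5% to 46.2%) in the oocyte, 41.0% (40.3% to 41.8%) in the zygote and 24.8% (24.01% to 25.7%) in spermatozoa had a position on 1 transcript where the 5′ ends overlap by 10 bases.

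**Figure D4:**
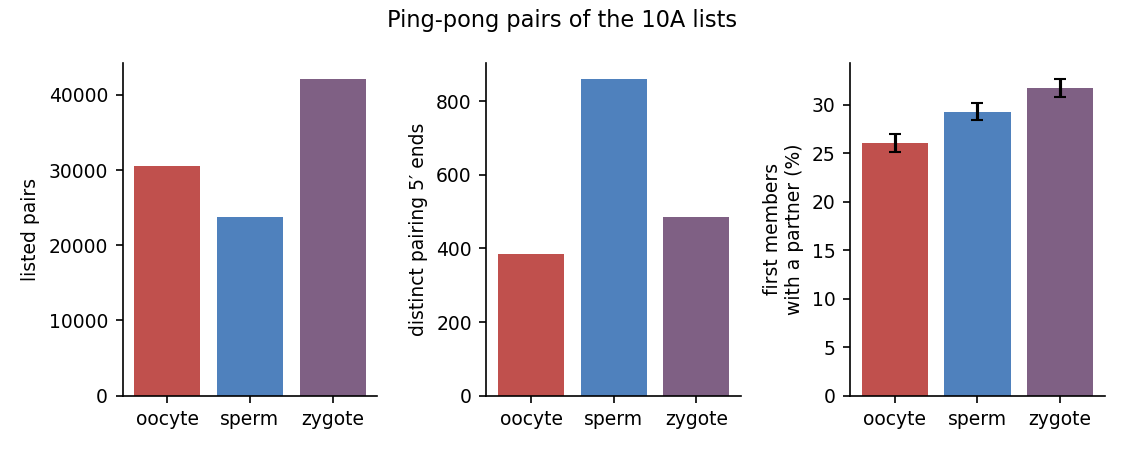
Listed pairs, distinct pairing 5′ ends, and the percent of distinct first members with a partner in the 10A lists of the 3 libraries, with 95% Clopper-Pearson intervals as bars in the last. The zygote list has the most pairs (42130) and the spermatozoal list the most distinct pairing 5′ ends (861).

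The pairs of the zygote were shared more with the oocyte than with spermatozoa. As pairs of identifiers, 757 of the 1652 in the zygote were also in the oocyte, and 202 were in spermatozoa. Of the piRNAs listed in both libraries, 581 were members of pairs in both oocyte and zygote, where independent lists of these sizes would share 185. Spermatozoa and zygote shared 399 members, against 181, and oocyte and spermatozoa 387, against 183. With all piRNAs of the pairs lists as the background, the expected numbers were 74.5, 380.2 and 361. So the excess of the comparisons with spermatozoa depends on the background.

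Some of the 10A reads matched a single gene. Among first members, antisense matches to CT010467.1, annotated as an rRNA gene, led in the oocyte with 1939 reads and in spermatozoa with 2665. The annotation lies on the minus strand (chromosome 17, 39846353 to 39848827), so these reads follow the plus strand. Which strand gives rise to rRNA there was not tested, so the matches need not be antisense to rRNA. In the zygote the matches to CT010467.1 had 1947 reads. D10Wsu102e, a protein-coding gene (GRCm38 chromosome 10, 83360221 to 83488505, plus strand), had 1798 sense reads among first members in the oocyte, 2666 in the zygote and 5 in spermatozoa. Among second members it had 266 sense reads in the oocyte and 10337 in the zygote, or 613 (541 to 691) and 16341 (16027 to 16659) per 1000000 second-member reads of the list. A second member is listed only with a partner, so this measures paired reads. Plcb1, which encodes a phospholipase C (chromosome 2, 134786067 to 135475258, plus strand), had 2402 sense reads in the oocyte and 3481 in the zygote among second members, or 5533 and 5503 per 1000000 second-member reads. By count, the commonest length of the second-member sense reads of Plcb1 was 21 nt in the oocyte and the zygote. For D10Wsu102e it was 25 nt in the oocyte and 21 nt in the zygote. In spermatozoa the long noncoding RNA Gm49794 had 982 sense reads among first members and D130017N08Rik 723, both with none listed in the oocyte or the zygote.

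Identifiers that mark the mitochondrial chromosome took a small share of either class. They held 0.0476% (0.0466% to 0.0487%) of the endo-siRNA signal in the oocyte, 0.0358% (0.0350% to 0.0367%) in the zygote and 0.913% (0.898% to 0.928%) in spermatozoa. For piRNAs the shares were 0.0396% (0.0388% to 0.0404%), 0.0356% (0.0348% to 0.0363%) and 0.105% (0.103% to 0.106%). Those marked as unplaced (chrUn) held 0.254% of the endo-siRNA signal in the oocyte, 3.04% in spermatozoa and 0.257% in the zygote, and the other identifiers carry no chromosome. Most deepBase piRNA numbers also stood in the endo-siRNA list of the same library, 91.8% in the oocyte, 79.1% in spermatozoa and 91.8% in the zygote.

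The spermatozoal 5U10A lists had no counterpart analysed here in the oocyte or the zygote. The RNAdb list held 32847 pairs among 24055 distinct sequences and the deepBase list 7971 pairs among 4967. These lists give a pair in both orders, unlike the 10A lists, so the distinct pairs are fewer. The end TGGGATTAAA and its complement TTTAATCCCA, for example, each gave 2626 RNAdb pairs. By count, 79.5% (79.4% to 79.7%) of the RNAdb reads were 25 to 32 nt long, and the commonest length was 29 nt in both lists. A partner at an overlap of 10 bases was found for 27.2% (26.6% to 27.8%) of the RNAdb sequences, against 16.6% to 21.2% at the 9 overlaps from 11 to 19 bases. For deepBase sequences it was 38.2% (36.8% to 39.5%), against 3.97% to 15.1%.

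**Figure D5:**
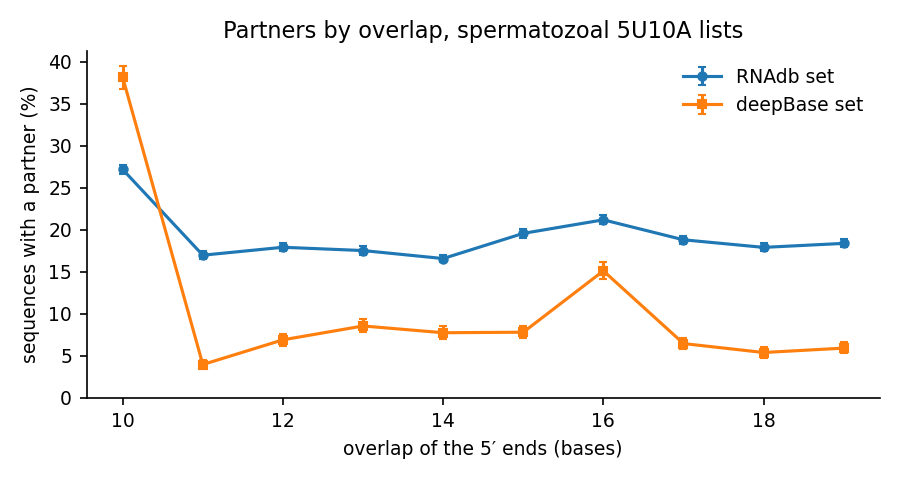
Percent of distinct sequences of the spermatozoal 5U10A lists that have a partner at each overlap of the 5′ ends in bases, with 95% Clopper-Pearson intervals as bars. The share is highest at 10 bases in both sets, at 27.2% for RNAdb and 38.2% for deepBase.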

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

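The tests in this part were chosen after the results were seen, except the thinning of the pairs lists to equal first-member reads.

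The spermatozoal 5U10A lists, which none of the comparisons between libraries use, held reads matching single genes far above the 3 counts that a count of 0 allows. This is what singled them out, but the 10A lists pass the same limit, for example with 2665 reads antisense to CT010467.1 in spermatozoa. So the flag marks lists outside the comparisons and not an unusual level. Only transcripts were searched, so these reads may also match elsewhere in the genome, such as repeats, and their origin was not tested. In the RNAdb list, 33122 reads matched the long noncoding RNA Gm5878 alone in the sense direction, 3774 matched the long noncoding RNA Gm21269 in the sense direction and 2932 matched Zfp445 in the antisense direction. In the deepBase list, 3297 reads matched Gm10800 alone in the antisense direction, 1386 matched Lars2 in the sense direction and 534 matched the mitochondrial tRNA gene mt-Th in the sense direction. With reads that match both Gm10800 and Gm10801 included, the reads matching these 2 genes in the antisense direction came to 10513. They were 23.0% (22.6% to 23.4%) of the deepBase list, and 0 in the other 4 lists. Those 4 lists hold RNAdb names only, so the 0 is no comparison with the oocyte or the zygote.

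The spermatozoal 5U10A sequences had a partner at an overlap of 10 bases more often than at other overlaps, and a few 5′ ends or genes could account for this. In the RNAdb set the share was 27.2%, above the highest of the 9 other overlaps (21.2%), and it was 25.1% without the 10 5′ ends in most pairs (highest other overlap 20.3%). In the deepBase set it was 38.2%, and 26.1% (24.9% to 27.4%) without reads that match Gm10800 or Gm10801 (highest other overlap 14.9%). So the 10 5′ ends in most pairs are not the whole cause in the RNAdb set, nor the reads of Gm10800 and Gm10801 in the deepBase set. Chance complementarity had no test apart from the excess itself, how the lists were selected is not given in the sources used here, and no biological explanation was tested.

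The zygote 10A list held the most pairs and the spermatozoal list the fewest, and both sequence variants and the number of reads could produce this order. With each pairing 5′ end counted once, the spermatozoal list came first with 861. With the lists thinned to the reads of the spermatozoal list, the zygote list held a median of 11734 pairs over 20 draws (10764 to 12995) and the oocyte list 14512, against 23775 in spermatozoa. Without the CA repeat the spermatozoal list had 13839 pairs, between these zygote and oocyte medians, and with at least 10 counts for both reads spermatozoa still had the fewest (600.0, against 2011 in the oocyte and 2021 in the zygote). The order thus depends on how pairs are counted, and whether a difference in ping-pong activity adds to it stays open.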

How the results depend on the processing

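The alternatives at least 1 read equivalent, collapsed identifiers, pairs with at least 10 counts, pairing 5′ ends, pairs without the CA repeat and shares weighted by counts were chosen after the data were seen.

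Of 273 alternatives over 68 results, 79 left the main results the same, 148 moved them and 4 reversed them; for differences between the numbers higher and lower, derived from those, 21 were the same, 15 moved and 6 reversed. The spermatozoal endo-siRNA profile had the lowest depth, at 1555582 read equivalents. No left-out replicate could be run with 1 library per group. Collapse by sequence or placement, and items with 1 placement, were not run, since the profiles give no sequences; equal adjacent identifiers were collapsed instead. Where construction does not show it, the cause was not tested.

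Fewer items are listed under a higher minimum by construction. piRNAs numbered 47818 in the oocyte, 30834 in spermatozoa and 47409 in the zygote at 5 counts, 36605, 19397 and 36560 at 10, and 50995 in spermatozoa at 2. Endo-siRNAs numbered 120434, 32106 and 124154 at 2 counts, 87343, 16465 and 91594 at 5, 64312, 9472 and 68588 at 10, and 83791, 64309 and 83186 at equal depth. With at least 1 read equivalent, spermatozoa listed 46021.

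By parental origin, in the order both gametes, oocyte alone, spermatozoa alone and neither, zygote piRNAs were 13.97%, 72.9%, 1.04% and 12.0% at 5 counts, 11.2%, 76.9%, 0.687% and 11.2% at 10, 81.9%, 18.0%, 0.0226% and 0.106% by signal, and 24.8%, 56.4%, 3.27% and 15.5% at equal depth. Collapsed, oocyte alone was 53.4% and neither 13.0%. Zygote endo-siRNAs were 7.93%, 76.6%, 0.712% and 14.7% at 5 counts, 5.21%, 78.9%, 0.478% and 15.4% at 10, 74.9%, 24.9%, 0.0285% and 0.156% by signal, 19.8%, 52.2%, 6.43% and 21.6% at equal depth, and 37.9%, 50.2%, 2.60% and 9.28% collapsed.

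For piRNAs, r between zygote and oocyte, zygote and spermatozoa, and oocyte and spermatozoa was 0.978, 0.204 and 0.270 with a pseudocount of 10, and 0.970, -0.109 and -0.0450 for items with at least 10 counts, so the last 2 reversed; rho was then 0.945, -0.480 and -0.427. Without the 10 most abundant items the r with spermatozoa was 0.0869 for the zygote and 0.131 for the oocyte. For endo-siRNAs, r was 0.965, 0.0916 and 0.118 with a pseudocount of 10, and 0.934, -0.130 and -0.0755 for items with at least 10 counts, again with the last 2 reversed; rho was then 0.856, -0.161 and -0.0708.

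For zygote against oocyte, piRNAs higher and lower were 141 and 63 at 2-fold, 1 and 2 at 8-fold (a reversed difference of -1), 107 and 35 at 20 RPM and 24 and 2 at 500 RPM, and 27 were higher with TMM factors. Endo-siRNAs were 42 and 54 at 2-fold, 1 and 2 at 8-fold, 54 and 216 at 20 RPM, and 1 and 2 at 500 RPM. They were 21 and 5 with median-of-ratios factors and 23 and 3 as deposited, reversed differences of 16 and 20 that come from the scaling. For zygote against spermatozoa, piRNAs were 4214 and 748 at 20 RPM and 208 and 53 at 500; endo-siRNAs were 4636 and 3487, and 55 and 306, with reversed differences of 1149 at 20 RPM and 27 as deposited. For oocyte against spermatozoa, piRNAs were 3465 and 662, and 133 and 39; endo-siRNAs were 4732 and 3394, a reversed difference of 1338, and 52 and 292.

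In the order oocyte, spermatozoa and zygote, pairs numbered 1211, 3294 and 1652 as pairs of identifiers, 2011, 600.0 and 2021 with at least 10 counts for both reads, and 386, 861 and 486 as pairing 5′ ends. Spermatozoa had 13839 without the CA repeat. The 5U10A deepBase list held 7971, but with pairs given in both orders, so this number is not like those of the 10A lists. Partner shares weighted by counts were 13.0%, 14.8% and 23.1%. Reads of 25 to 32 nt were 35.4%, 55.1% and 33.1% with distinct sequences counted once and 42.5%, 52.9% and 37.6% without the 10 most abundant; a first base of A was 47.3%, 31.7% and 49.1%, and 59.1%, 36.7% and 60.9%. As members in place of pairs, zygote and oocyte shared 399 and 387 with spermatozoa. Against all piRNAs of the pairs lists, the expected members were 74.5 for oocyte and zygote, 380.2 for spermatozoa and zygote and 361 for oocyte and spermatozoa. With each item counted once, identifiers marked chromosome M were 0.342%, 0.465% and 0.306% of piRNAs and 0.501%, 1.24% and 0.519% of endo-siRNAs.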

Other observations

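The tests in this part were all chosen after the results were seen.

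Other abundant piRNAs were shared by the oocyte and the zygote at levels within 4-fold. PIR75142 had 53119 RPM in the oocyte, 33623 in spermatozoa and 43114 in the zygote. PIR232912 had 20043 RPM in the oocyte and 32070 in the zygote, against 11 in spermatozoa, and mmur001201421 had 20986 and 24079, against 7.40. PIR235614 had 9529 RPM in the oocyte and 19396 in the zygote, 2.04-fold (2.03 to 2.05). Of the distinct first members of the zygote 10A list, 47.5% were also in the oocyte list, with 98.1% of the reads, and 11.8% in the spermatozoal list, with 77.3% of the reads.

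piRNAs and endo-siRNAs listed in the zygote and spermatozoa but not in the oocyte might have been carried in by spermatozoa. At equal depth, 2585 piRNAs were listed in zygote and spermatozoa alone, and 3032 in the unfertilized oocyte and spermatozoa alone. For endo-siRNAs the numbers were 5346 and 7583, but as listed they were 5672 and 5326, so the order turns. With the oocyte and zygote alone brought to the same depth they were 6117 and 11130.0, and for piRNAs 3109 and 3994, so at equal depth the zygote showed no excess by number in either class. These draws take whole reads, so they also drop identifiers with a fraction of a read, and the 2 effects were not separated for endo-siRNAs. A smaller carry-over stays open, since oocyte RNAs can be lost after fertilization.

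The summed levels of small RNAs with at least 100 RPM in spermatozoa, and at least 64 times the mean of oocyte and zygote, were also compared. The ratio of zygote to oocyte was 0.658 for 97 piRNAs, 0.846 without mmur000042018, and 0.744 for 609 endo-siRNAs, or 1.19 on the deposited scale. These items were chosen with the zygote level included, which leaves out any item carried in at a high level, so the ratios decide nothing about carry-over.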
